A study of Apis mellifera with 2 samples.

How the data were processed

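Small RNA was sequenced from pooled larvae of the 2 honey bee castes. Per the labels' protocols, each queen laid for 24 h, and larvae were moved to queen cups at 66 h. The larvae moved were less than 18 h after hatching, so the 66 h is not an age after hatching. Collections were at 73 to 90 h, 97 to 114 h and 121 to 138 h after hatching. RNA was extracted with Trizol, about equal amounts from the 3 days were pooled within each caste, and a gel fraction of 18 to 30 nt was taken. A 5' adapter and then a 3' adapter were ligated, followed by RT-PCR and Solexa sequencing. Adapter ligation and PCR favour some sequences, so counts of different miRNAs in a library do not measure their molar ratio.

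The values used were whole-number counts per miRNA as deposited by the authors, with 1 column for each caste and 692 entries. The aligner, the miRNA caller, the genome build, the miRNA annotation and the treatment of reads that fit several miRNAs are not given in the sources used here. Of the entries, 53 carry honey bee miRNA names and 639 are marked as predictions, numbered 1 to 639, and are called predicted entries with that number. No name occurred more than once, arms were not told apart and no sequences were given, so arm use, sequence variants and sums per precursor were not computed. The table has 242 further columns with 0 filled cells. All 53 named miRNAs matched names in the RefSeq gene table of assembly Amel_HAv3.1, which served for names and for which miRNAs lie within 10 kb of each other, and none of its coordinates are printed.

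Libraries were scaled to their totals of listed counts, 2658259 for queen and 2318675 for worker, so that 1 count equals 0.376 and 0.431 CPM (counts per 1000000 listed counts). The measure was the ratio of CPM, queen over worker or worker over queen as stated. Its exact conditional (Clopper-Pearson) 95% interval covers counting error only and treats each read as an independent molecule. PCR reads without molecular identifiers are not independent molecules, so the interval may be too narrow even for counting error. An entry was called higher in a caste when the ratio was at least 2 (or at most 0.5) and the interval excluded 1, among entries with at least 20 counts over both libraries. This left 49 named and 87 predicted entries, and the 4 named miRNAs left out had at most 12 counts each. For calling and ranking, a count of 0 was replaced by 3 counts (1.13 CPM in the queen library and 1.29 CPM in the worker library), and no fold is printed for such entries.

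The text names the 10 most abundant miRNAs by mean share, up to 10 called entries per direction with the largest ratio among those with at least 100 counts, and members of the fixed lists. Only 6 entries met this in the queen direction. The design, the 16 lists, the naming rule and the alternatives were set before the data were examined, except that counting only entries present in both libraries was added after seeing the data. The lists were the let-7 complex, the mir-2, mir-9, mir-34, mir-275 and mir-12 clusters, the mir-92, mir-279 and mir-263 families, muscle, nervous system, growth and metabolism, Hox, germline, midgut, and miRNAs first described in the honey bee. For the 6 lists with at least 3 assessed members, the median log2 ratio was ranked among 10000 random lists of the same size, matched on mean share in 3 classes. Smaller lists are given as values.

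Alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 median of ratios, totals without the 5 most abundant miRNAs, no minimum or 100 counts, ratios of 1.5 and 4, a 99% interval and named miRNAs alone. Both packages supplied scaling factors and no tests. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The calling step was tested on simulated queen and worker libraries of all entries, of which 135 reached 20 counts. The simulated counts varied by counting error alone, with no further variation between libraries. It called 19 of 20 entries changed 3-fold, 19 of 20 changed 5-fold and 0 of 95 unchanged ones. The intervals of unchanged entries covered a ratio of 1 in 93.7% with the true depths. With the simulated totals, which changed entries shifted by −0.06 on the log2 scale, coverage was 74.7%. Thus the intervals of well-counted miRNAs understate the uncertainty from scaling. In the data the scalings shifted log2 ratios by up to 0.52, so the calls and coverage of the simulation are a best case.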

Results

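The data were small RNA counts from honey bee (Apis mellifera ligustica) larvae that were being reared as queens or as workers. Per the labels, larvae came from 3 colonies of a strain bred for high royal jelly yield. In each colony 150 larvae less than 18 h after hatching were moved into queen cups to become queens. From each colony 40 to 60 larvae of each caste were taken on days 4, 5 and 6, which spanned 73 to 138 h after hatching. RNA of the 3 days was combined into 1 queen library and 1 worker library. The queen library held 2658259 listed counts and the worker library 2318675, a ratio of 1.15. The table listed 53 named miRNAs and 639 predicted ones. There were no replicates, so no p-values were computed. Every interval is a 95% interval that covers counting error only, with each read taken as an independent molecule. The ratios compare these 2 libraries, and how far queen and worker larvae vary between colonies was not measured.

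The first comparison asked which miRNAs made up the listed miRNA counts of each caste. miR-275 was the most abundant in both libraries, at 39.0% of queen counts (38.9 to 39.0) and 33.8% of worker counts (33.7 to 33.9). miR-1, a muscle miRNA conserved across animals, took 15.0% of queen counts and 18.0% of worker counts. miR-184 took 16.4% and 14.4%, and miR-305, which neighbours miR-275 in the genome, took 8.69% and 5.82%. These 4 miRNAs together made up 79.1% of queen counts (79.0 to 79.1) and 72.0% of worker counts (72.0 to 72.1). The next 6 by mean share were miR-996, miR-31a, miR-71, miR-276, miR-8 and let-7. miR-31a took 2.24% of queen counts against 4.99% of worker counts, and miR-71 took 1.17% against 2.90%. let-7, a regulator of developmental timing, took 1.42% of queen counts and 0.849% of worker counts. miR-996 took 4.19% and 3.96%, miR-276 took 2.16% and 1.90%, and miR-8 took 1.25% and 1.45%. These 10 miRNAs held 91.5% of queen counts (91.5 to 91.5) and 88.0% of worker counts (88.0 to 88.1). They were ranked by mean share, and in the worker library alone let-7 lay below miR-283 (1.16%), miR-993 (0.996%) and predicted entry 24 (0.968%), the last chosen after its values were seen. Shares are of a library's listed counts, not of all its small RNA reads, and carry exact Clopper-Pearson intervals. A share depends on all other miRNAs of its library, so a larger share does not by itself show more molecules per larva.

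**Figure D1:**
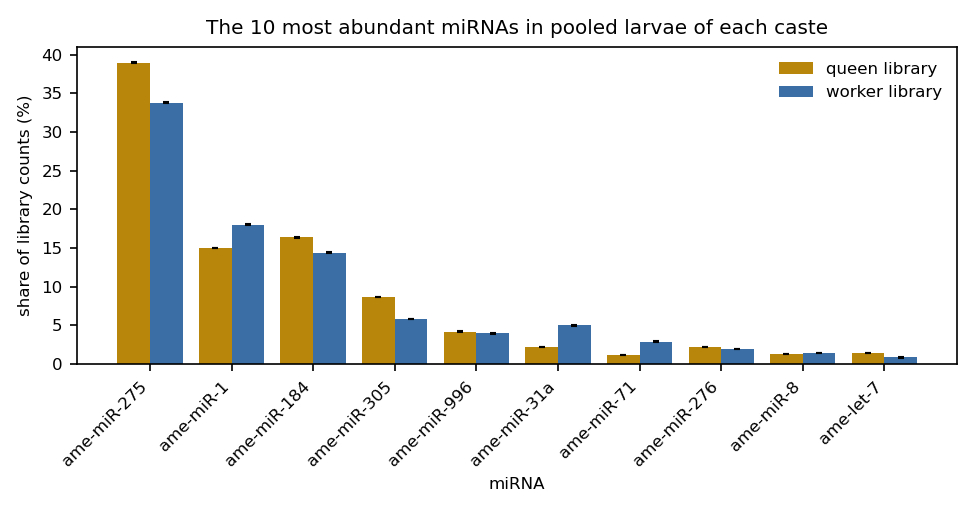
Share of each library's listed counts, in percent, taken by the 10 miRNAs with the highest mean share. Values are for the queen and the worker library, with exact 95% counting intervals as error bars. miR-275 leads in both, at 39.0% and 33.8%, and miR-31a and miR-71 take larger shares of the worker library.

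The second comparison asked which named miRNAs differed between queen and worker larvae. miR-375 was 2.85-fold higher in the queen library (2.76 to 2.93), with 18879 counts against 5784. It was the 1 named miRNA at least 2-fold higher there. In the worker library 12 named miRNAs were at least 2-fold higher, led by miR-124, a miRNA of neurons, at 5.72-fold (5.22 to 6.28). miR-263, which matched Mir263a in the RefSeq annotation and whose Drosophila counterpart protects sensory bristle cells, was 5.37-fold higher in the worker library (5.17 to 5.58). Its relative miR-263b was 3.92-fold higher, a log2 ratio of queen over worker of −1.97 (−2.37 to −1.59), with 71 counts in the queen library and 243 in the worker library.

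miR-92b was 3.77-fold higher in the worker library (3.58 to 3.97), and miR-133, a muscle miRNA, was 3.51-fold higher (2.50 to 5.01) on 46 and 141 counts. miR-13b was 3.35-fold higher (3.20 to 3.51) and miR-7 3.31-fold higher (3.08 to 3.56). miR-281 was 2.98-fold higher (1.75 to 5.27) on 20 and 52 counts. miR-190, which fell outside the naming rule and was chosen after its values were seen, was 3.02-fold higher (2.91 to 3.13). miR-71 was 2.46-fold higher (2.43 to 2.50), miR-277 2.35-fold (2.01 to 2.76) and miR-31a 2.23-fold (2.21 to 2.25) higher in the worker library with scaling to the total. These last 3 fell under 2-fold with each of the 3 other scalings, where miR-31a stood at a log2 ratio between −0.73 and −0.63. The other 9 stayed at least 2-fold higher in the worker library under all 4 scalings, and miR-375 stayed higher in the queen library. let-7 had a log2 ratio of queen over worker of 0.74 (0.71 to 0.76), miR-305 of 0.58 (0.57 to 0.59) and miR-315 of 0.74 (0.60 to 0.87). These 3 were not at 2-fold in the main scaling and passed it in the queen direction with each of the 3 others. miR-305 passed narrowly, at log2 ratios of 1.003, 1.04 and 1.10, and the last scaling left its own counts out of the totals. The TMM and median-of-ratios factors were computed from all entries, predicted ones included. The calls of miR-305 with these 2 scalings therefore hang on small differences in the factors. miR-315 was also chosen after its values were seen.

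Of the 49 named miRNAs with at least 20 counts, 36 were not at 2-fold in either direction and 25 lay within 1.5-fold. The median log2 ratio of these 49 was −0.36, with 12 above 0 and 37 below. TMM factors raised every log2 ratio by 0.43, median of ratios by 0.46 and totals without the 5 leading miRNAs by 0.52. The median then became 0.07, 0.10 and 0.16, and the counts above and below 0 became 26 and 23, 26 and 23, and 27 and 22. TMM factors and median of ratios place the typical entry near a ratio of 1. A median near 0 therefore follows from them and does not test whether most miRNAs were unchanged. The split of named miRNAs at 2-fold moved from 1 queen and 12 worker to 4 and 9, 4 and 9, and 5 and 9. Differences from the median named miRNA do not depend on the scaling. On the log2 scale they were 1.87 for miR-375, 1.10 for let-7, −2.16 for miR-124 and −2.07 for miR-263. The ratio of 15 named miRNAs changed sides of 1 under at least 1 scaling, among them miR-1, miR-8, miR-34, miR-100, miR-125, miR-317 and bantam. Across the 49 named miRNAs, which are not independent replicates, log2 CPM (counts per 1000000 listed counts) of the libraries had a Pearson r of 0.978 and a Spearman rho of 0.973. How reads that fit near-identical relatives were counted is not given in the sources used here, so the values of miR-263 and miR-263b, miR-92a and miR-92b, miR-2, miR-13a and miR-13b, and miR-279 and miR-996 are uncertain.

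**Figure D2:**
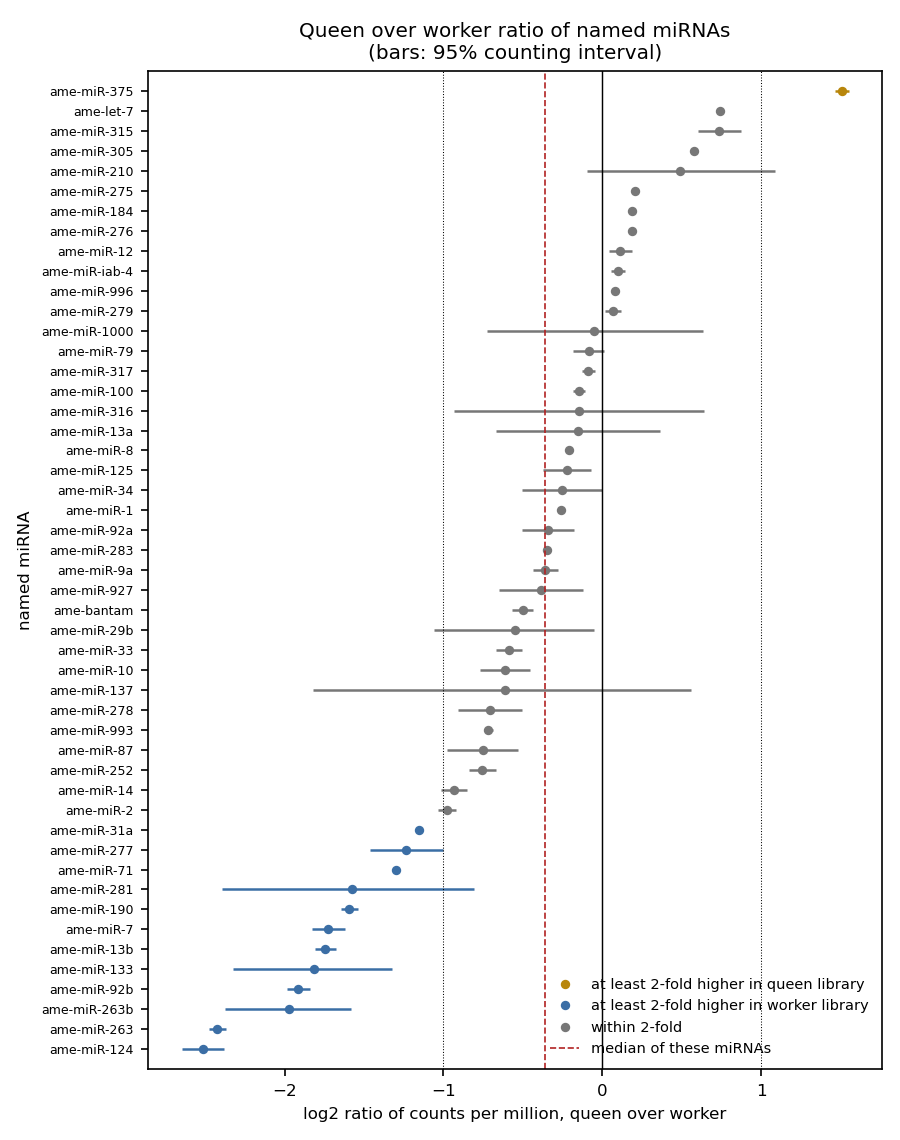
Log2 ratio of CPM, queen over worker, for the 49 named miRNAs with at least 20 counts, with 95% counting intervals as bars, dotted lines at 2-fold and a dashed line at their median of −0.36. With scaling to the total, miR-375 lies above 2-fold and 12 miRNAs lie below it on the worker side, of which miR-31a, miR-71 and miR-277 move inside 2-fold with the other scalings.

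The third comparison took the named miRNAs by lists fixed before the data were examined. Of the nervous-system list, 2 of 3 assessed members were higher in the worker library, miR-124 and miR-7, while miR-137 had a log2 ratio of −0.61 (−1.82 to 0.56) on 12 and 16 counts. The list's median was −1.73, at the 8.12th percentile of random lists. miR-932 had 4 and 8 counts and miR-219 had 0 and 2, too few to assess. Both members of the miR-263 list were higher in the worker library, miR-263 at −2.42 and miR-263b at −1.97. In the muscle list miR-133 was higher in the worker library at −1.81, and miR-1 had −0.26, a direction that turned with the 3 other scalings. In the midgut list miR-281 was higher in the worker library at −1.58, and miR-275 had 0.21.

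In the mir-2 family and cluster, 2 of 4 members were higher in the worker library, miR-13b at −1.75 and miR-71 at −1.30. miR-2 had −0.98 and miR-13a had −0.15 (−0.67 to 0.36), and the list's median of −1.14 lay at the 10.9th percentile. With the other scalings miR-71 lost its call, which left 1 of 4 members, the median lay between −0.71 and −0.62, and the direction of miR-13a turned. In the mir-34 cluster miR-277, which in Drosophila controls branched-chain amino acid breakdown, was higher in the worker library at −1.23, a call lost with the other scalings. miR-34 had −0.25 and miR-317 had −0.09, and the list's median of −0.25, at the 64.5th percentile, turned positive with the 3 other scalings, as did both of these values. Of the 6 miRNAs tied to growth and metabolism in Drosophila, miR-277 was the 1 at 2-fold. miR-14 had −0.93, miR-278 −0.71, miR-33 −0.59, bantam −0.50 and miR-8 −0.21, the last 2 turning positive with at least 1 other scaling. The list's median was −0.65, at the 35.5th percentile, and lay between −0.22 and −0.12 with the 3 other scalings.

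The let-7 complex had 0 of 3 members at 2-fold with scaling to the total. let-7 had 0.74, miR-100 −0.15 and miR-125 −0.22, so that the list's median was −0.15, at the 57.5th percentile, and its mean was 0.12. That median and both negative values turned positive with the 3 other scalings. The Hox list also had 0 of 3 at 2-fold, with miR-993 at −0.72, miR-10 at −0.61 and miR-iab-4 at 0.10. Its median of −0.61 lay at percentile 20.2, and became −0.19 to −0.09 with the 3 other scalings. Both members of the miR-275 and miR-305 list were short of 2-fold, at 0.21 and 0.58, as were miR-279 at 0.07 and miR-996 at 0.08. The same held for miR-12 at 0.11 and miR-283 at −0.35, and for miR-79 at −0.09 and miR-9a at −0.36, where the 3 negative values turned with the other scalings. In the mir-92 family miR-92b was higher in the worker library at −1.91 and miR-92a had −0.34, which also turned. miR-184, the 1 listed germline member, had 0.19, and of the miRNAs first described in the honey bee 0 were listed.

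Over all lists 10 of 37 assessed members were at 2-fold, 0 in the queen direction and 10 in the worker direction, and this became 2 and 8 with each other scaling. None of the 6 lists with at least 3 assessed members had a median outside the middle 95% of random lists. Lists of 3 to 6 miRNAs give a coarse comparison, and percentiles describe these 2 libraries.

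The fourth comparison concerned the predicted miRNAs, which are given by their number in the table. Predicted entry 39 had 2125 counts in the worker library and 0 in the queen library, and predicted entry 40 had 451 and 0. In the queen direction, predicted entries 414, 252 and 265 had 356, 341 and 146 queen counts and 0 worker counts. No fold is given for these 5, since whether a 0 stands for no reads or for an entry not listed in that library is not given in the sources used here. Among predicted entries counted in both libraries, 36 was 8.69-fold higher in the worker library (6.35 to 12.1) and 66 was 7.38-fold higher (5.25 to 10.6). Predicted entry 11 was 4.49-fold (3.68 to 5.52), 18 was 4.42-fold (3.13 to 6.37) and 9 was 3.79-fold (3.58 to 4.01) higher there. Predicted entry 28 was 3.07-fold higher in the queen library (2.35 to 4.04) and predicted entry 1 was 2.41-fold higher (2.20 to 2.64).

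Predicted miRNAs held 3.36% of queen counts (3.34 to 3.38) and 4.76% of worker counts (4.73 to 4.78). Of 87 predicted entries with at least 20 counts, 14 were called higher in the queen library and 27 in the worker library. Of these, 9 and 6 had counts in 1 library alone. With 0 replaced by 3 counts, any such entry with at least 20 counts is called, so these calls show no measured fold. Together with the named miRNAs, all calls came to 15 in the queen direction and 39 in the worker direction among 136 assessed entries. They came to 6 and 33 when only entries with counts in both libraries were taken. With entries in 1 library included, the split became 20 and 30 with TMM factors and 20 and 29 with median of ratios. Without the 5 leading miRNAs it was 21 and 28. The predicted entries carry no sequence or position in the table, so their identity was not checked.

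**Figure D3:**
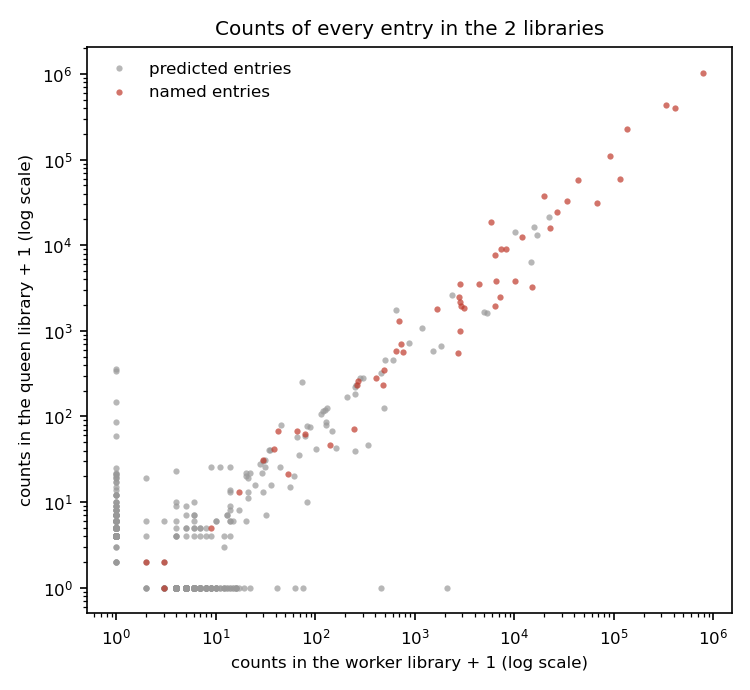
Counts plus 1 of each of the 692 entries in the worker library (horizontal, log scale) and in the queen library (vertical, log scale), with named and predicted entries in separate colours. Most named miRNAs lie near the diagonal, while miR-124 and miR-263 lie toward the worker side. On an axis, with 0 counts in 1 library, lie 526 predicted entries and the named miR-219 (0 queen and 2 worker counts).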

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

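Counting only entries present in both libraries was chosen after seeing the data; the other alternatives were set before. Of 12 predicted entries named for their large ratios, 5 had 0 counts in 1 library, which fixed their call in advance. Single ratios were those of these 12 and of 49 named miRNAs. Of these ratios, 55 kept their side of the 2-fold threshold with TMM factors, 55 with median of ratios and 54 without the 5 leading miRNAs; 3, 3 and 4 gained a call, 3 lost one with each, and 0 calls reversed. Of 26 calls among the 72 predicted entries assessed with counts in both libraries, 6, 7 and 8 were lost with these scalings, and 2 were gained with each. Among all entries, those higher in the queen library (15) became 39 with no minimum count, 6 with a minimum of 100 counts, 1 with named miRNAs only and 6 with entries present in both libraries. Those higher in the worker library (39) became 111 with no minimum, 25 with a minimum of 100, 16 at a ratio of at least 4 and 13 with named miRNAs only. With named miRNAs only, the totals were also those of named entries, 2568876 for queen and 2208402 for worker. The 13 therefore differs from the 12 named calls with totals of all entries. Named miRNAs higher in the queen library (1) became 4 with TMM factors, 4 with median of ratios, 5 without the 5 leading miRNAs, 3 at a ratio of at least 1.5 and 0 at 4. Named miRNAs higher in the worker library (12) became 20 at 1.5 and 2 at 4. These changes follow from fewer or more entries assessed, from the threshold, or from adding a constant to every log2 ratio. With miR-275 left out of both the sum and the total, the share of the leading miRNAs was 86.1% of queen and 81.9% of worker counts, and the 10 held 94.7% and 92.4% of named counts, where the total was smaller. The 99% interval left all counts of calls within 1.5 times. Sums per precursor, arm use and sequence variants were not run, since the table lists no arms or sequences. No paired analysis was possible because each caste has 1 library, which also rules out leaving a library out. Depth limits the entries with few counts: miR-281 and miR-137 rest on 72 and 28 counts.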

Other observations

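The tests on entries in 1 library, on well-counted miRNAs, on miR-124 against miR-7 and on neighbouring miRNAs were chosen after the results were seen, whereas totals without the 5 leading miRNAs were a planned scaling whose bounds were set after its values were seen. The bounds for neighbouring miRNAs and for nervous tissue were rewritten after their values were known.

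Several abundant predicted entries differed little between the castes. These entries, and the miRNAs named next, were chosen after their values were seen. Predicted entry 24 had 21611 queen and 22437 worker counts, a ratio of queen over worker of 0.840 (0.825 to 0.856). Predicted entry 5 had a ratio of 0.896 (0.877 to 0.916) and predicted entry 29 of 1.21 (1.18 to 1.24). Their log2 ratios, −0.25, −0.16 and 0.27, lie within the 0.52 by which the scalings differ, so the first 2 directions turn with another scaling. Predicted entry 15 was 2.61-fold higher in the worker library (2.54 to 2.69) on 6430 and 14660 counts with scaling to the total, and fell under 2-fold with each of the 3 other scalings. Among named miRNAs outside the lists, miR-252 was 1.69-fold higher in the worker library (1.59 to 1.79), and miR-210 had a ratio of queen over worker of 1.40 (0.937 to 2.13) on 66 and 41 counts, and passed 2-fold in the queen direction without the 5 leading miRNAs in the totals, at a log2 ratio of 1.01.

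Of 639 predicted entries, 526 had counts in 1 library alone, 208 in queen and 318 in worker. A chance split of their reads was computed at the 45.2% queen share of counts in predicted entries present in both libraries. It would leave 86.1 such entries, with an upper limit of 102, which argues against a chance split of independent reads. PCR copies of the same molecule are not independent and would raise these limits. Of the 526 entries, 15 had 1 or 2 counts, whereas 388 had 3 to 5 counts. Along the table's numbering the 526 entries formed 32 runs of the same library, where 10000 shuffles gave a median of 252 and a minimum of 209. This is consistent with entries having been listed separately for each library, so that a 0 may mean not listed in that library. Caste-specific small RNAs stay open for the 15 single-library entries with at least 20 counts, such as predicted entries 39 and 414, because 1 library per caste gives no replicate check. Of the 49 assessed named miRNAs, 0 had counts in 1 library alone. Of these 49, 35 had at least 1000 counts, so they are no like comparison for the predicted entries.

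The median named miRNA was lower in the queen library, at a log2 ratio of −0.36. Few counts do not account for it, since the 35 named miRNAs with at least 1000 counts had a median of −0.34. The share taken by miR-275, miR-1, miR-184, miR-305 and miR-996, 83.3% of queen and 76.0% of worker counts, may account for it, since without them in the totals the median was 0.16. That value overshoots 0. Wherever the median falls, relative counts cannot tell a scaling effect from a true difference in total miRNA without a spiked-in standard. The difference between the castes in total miRNA was not tested.

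The nervous-system list had a median log2 ratio of −1.73, inside the range of random lists (−1.81 to 0.07, percentile 8.12), with miR-124 and miR-7 called lower in the queen library and miR-137 not, so what follows concerns these miRNAs and no change of the list as a whole. Leaving the 5 leading miRNAs out of the totals moved the median, which is the value of miR-7, to −1.20, and both calls stayed, which argues against that share as their whole cause. A smaller share of nervous tissue in the pooled queen larvae is a candidate explanation that cannot be told apart from lower miR-124 in the same tissue. The log2 ratio of miR-124 minus that of miR-7 was −0.79 (−0.96 to −0.62), whereas a shared tissue effect would lower both alike if both were made in nervous tissue alone. miR-7 is also made in other tissues and miR-137 had 28 counts, so this difference excludes nothing.

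A further hypothesis was that miRNAs within 10 kb of each other, which may share a precursor transcript, have similar ratios. Their mean absolute log2 difference was 0.68 over 13 neighbouring combinations of 15 miRNAs in 6 clusters, against a median of 0.95 and a 5th percentile of 0.58 for shuffled ratios. It lay at the 13.0th percentile, between the bounds set, so the hypothesis was neither borne out nor excluded. Neighbours with similar log2 ratios were miR-279 and miR-996, at 0.07 and 0.08, and miR-125 and miR-100, at −0.22 and −0.15. miR-275 and miR-305 had 0.21 and 0.58. Further apart lay miR-277 and miR-34, at −1.23 and −0.25, and let-7, at 0.74, from its neighbour miR-125. miR-13a and miR-13b, in the same cluster, had −0.15 and −1.75. These examples were chosen after their values were seen.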
